A study of Mus musculus with 12 samples.

How the data were processed

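Mouse (C57BL/6J) zygotes were microinjected with a LINE1 ASO or an RC ASO at 0.75 mM, per the labels, and embryos were collected at early 2C, about 33 h after hCG and 9 h after injection, or at 4C after 2 days of culture. RNA was extracted with a column kit and 500 pg was made into stranded total RNA libraries, sequenced as single-end 50 nt reads on 2 lanes, per the labels' protocols. What RC stands for is not given in the sources used here. The deposited values are raw read counts per gene, in 1 table per stage with 23284 genes each and 1 column per library. The submitters' processing notes name Trim Galore 0.4.0, TopHat2 2.0.9, R 3.3.0, DESeq2 1.12.3 and the build mm9, without saying which step each served. The names of the deposited tables carry the word featureCounts; its version, annotation and strand setting are not given in the sources used here. Reads of overlapping or antisense genes, of multigene families (Dux, Zscan4, Tdpoz, Usp17l, Eif1a-like, Obox and histone genes) and of genes with processed pseudogenes, such as those of ribosomal proteins, may therefore have been split or lost, and their values are uncertain. Retrotransposon RNA, LINE1 included, was not analysed here. No coordinates are given, because the reference used here for transcript length and GC content is of another build (GENCODE M21 on GRCm38); 20882 symbols matched it directly and 1943 through 1 synonym, so that 22825 genes had a value.

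Libraries were grouped by stage and ASO from the labels, 3 per group. The total per library, 19160716 to 51854939 counts, limits the precision for genes with few counts. Replicates also differed by more than counting error, and the sources of this spread, such as library preparation, were not separated. The 2 LINE1 ASO comparisons were fitted within each stage on 6 libraries; development (4C against early 2C in RC embryos) and the stage by ASO interaction were fitted on all 12, which then share 1 estimate of the spread. Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, a robust quasi-likelihood fit and F-test, and Benjamini-Hochberg adjustment over all tested genes with a threshold of 0.05. Every adjusted p of a gene in the text comes from this test unless DESeq2 is named, and the SE of a log2 fold change is its size divided by the square root of F. CPM values use the TMM factors of the fit concerned. A fold against a group with 0 counts is set against a floor of 3 counts over the group, and a group with 1 to 3 counts has a ratio with a 95% counting interval.

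The main tests, the alternatives listed below except the last, the gene lists and the rule for named genes were chosen before the data were examined; tests added later are named as such where they are reported. For the LINE1 ASO comparisons the rule took the 8 largest increases and 8 largest decreases among called genes with a mean of at least 50 counts per library and no overlap between the groups. Predicted or clone-named genes, snoRNA, miRNA and rRNA genes were left out. From each list passing camera it added the 3 members with the smallest p, and from other lists at most 2 called members. Dux, Zscan4c, Zscan4d, Zfp352, Ncl, Trim28, Rn45s, Pou5f1 and Cdkn1a were named always. Development and the interaction took 5 genes per direction, the interaction with no condition on overlap. Of 20 lists, those with at least 5 tested genes were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, all adjusted over the lists of a comparison. Camera compares a list with the other genes. The directional p of fry asks whether a list's genes move on balance 1 way and its mixed p whether they change in either direction, and neither compares the list with other genes. Fry passed 0 lists at early 2C, 1 at 4C, 17 in development and 2 in the interaction (stress response and cell cycle, adjusted p = 0.0485 each), and its mixed form 1, 11, 19 and 12.

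The LINE1 ASO effect at 4C was correlated with the developmental change over genes, using means of log2 CPM with a prior count of 2. Because both contrasts use the 4C RC libraries, 100 data sets with no LINE1 ASO effect were simulated, with 50 more for the overlap of calls, added after the data were seen, and the contrasts were also computed with no shared library. The alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals, no and a stricter low-count filter, leaving out the 20 most abundant genes, a replicate block, a fit without robust dispersion, a joint fit at each stage, an effect-size threshold, and leaving out each library. A correction for transcript length and GC content was run for the early 2C lists only and was added after the data were seen.

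The gene tests were tested on simulated counts in which 50 genes each were changed by 1.5, 2, 4 and 8-fold. EdgeR recovered 54, 64, 80 and 90% of them at early 2C (13625 genes), 2, 22, 68 and 78% at 4C (14231 genes), 6, 20, 58 and 76% in development and 2, 2, 52 and 60% in the interaction (15760 genes each). False calls numbered 6, 7, 5 and 2. A list of 40 genes shifted by 0.5 log2 had a camera p of 3.08e-12 at early 2C, 5.16e-12 at 4C, 1.4e-11 in development and 2.59e-06 in the interaction, and of 50 unshifted lists 0, 0, 0 and 1 passed 0.05. Each gene was simulated on its own, so these lists held no correlation between genes. In the measured data the estimated correlation of the ribosomal protein list was 0.476 at early 2C and 0.684 at 4C. The simulated lists therefore do not show how often camera passes unshifted lists of correlated genes. For the relation to development, a covariance of -0.817 put into 15344 genes was recovered as -0.756, and 5% of early 2C RNA mixed in as 4.87%.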

Results

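Gene expression was measured by total RNA sequencing in mouse embryos whose zygotes had been microinjected with an antisense oligonucleotide (ASO) against LINE1, the most abundant autonomous retrotransposon of the mouse genome, or with a control ASO that the labels call RC. Embryos were collected at the early 2-cell stage (early 2C), about 9 h after injection, or at the 4-cell stage (4C), after 2 days of culture. Each of the 4 groups held 3 libraries, 12 in all. The total count per library was 25803112, 28861666 and 29131716 in early 2C RC, and 51854939, 27374708 and 31340610 in early 2C LINE1 ASO. It was 21030581, 19160716 and 24249661 in 4C RC, and 24202425, 25101276 and 24641722 in 4C LINE1 ASO. LINE1 RNA itself, the target of the ASO, was not analysed here, so these values hold no check of the knockdown. Nothing in the labels says that replicates were separate pools of embryos or came from separate animals, so the p-values measure the spread between these libraries, which may be technical. No spike-in is stated, so every value is relative to the other genes of its library.

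Ccdc82 was the most abundant gene in each early 2C library, with 4.94% to 5.62% of the counts, and the ribosomal RNA precursor gene Rn45s in each 4C library, with 4.13% to 5.61%. Log2 CPM values correlated at 0.968 to 0.979 within early 2C RC, 0.983 to 0.986 within early 2C LINE1 ASO, 0.943 to 0.958 within 4C RC and 0.942 to 0.964 within 4C LINE1 ASO, across genes. Between early 2C RC and 4C RC libraries the correlation was 0.36 to 0.404. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom of 14.7 to 86.8. Of the 4C LINE1 ASO libraries, replicate 3 lay nearest to the RC libraries: Dux stood at 1.41 CPM in it, against 45.4 and 48.2 CPM in LINE1 ASO replicates 1 and 2 and 0.108 to 0.904 CPM in the RC libraries.

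The first comparison asked which transcripts differed between LINE1 ASO and RC embryos at early 2C. Prkab1, a regulatory subunit of AMP-activated protein kinase, rose from 64.2 ± 15.5 to 167 ± 19.3 CPM (SD, n = 3), a log2 fold change of 1.38 (SE 0.141; adjusted p = 7.59e-05, edgeR). Dcp1a, an activator of mRNA decapping, rose from 630 ± 79.3 to 1386 ± 220 CPM (log2 1.14, SE 0.113; adjusted p = 4.24e-05, edgeR), and the PHD-finger protein gene Phf13 rose by 1.04 (SE 0.110; adjusted p = 6.36e-05, edgeR). Pdia4, a protein disulfide isomerase of the endoplasmic reticulum, was lower, at 68.2 against 114 CPM (log2 -0.74, SE 0.123; adjusted p = 0.00657, edgeR). G6pdx, the gene of the first enzyme of the pentose phosphate pathway, was lower, at 501 against 785 CPM (log2 -0.65, SE 0.107).

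In all, 37 genes were higher and 13 lower among 13625 tested (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05). Among genes that met the naming rule (a mean of at least 50 counts, no overlap between the groups, clone-named genes left out), the other 5 of the 8 largest increases were Zfp866 (log2 1.117), Stard5 (0.93), Ccdc117 (0.88), Atl3 (0.87) and Sh3bgrl2 (0.84). The other decreases among the 8 largest under that rule were Ccdc130 (-0.94), the actin-remodelling gene Flii (-0.80), Stk32b (-0.79), the pre-mRNA cleavage endonuclease Cpsf3 (-0.77), the liver X receptor gene Nr1h2 (-0.71) and the centrosomal Cep250 (-0.58). Dux, the transcription factor that activates cleavage-stage genes, differed by 0.08 (SE 0.165; adjusted p = 0.952, edgeR), with 28.0 ± 3.96 CPM in RC. Zscan4c (-0.56), Zscan4d (-0.70), Zfp352 (-0.07), Ncl (0.01), Trim28 (0.04), Rn45s (0.05), Pou5f1 (-0.31) and Cdkn1a (0.14) did not pass the test either. At an unadjusted p under 0.05 there were 1205 genes, 8.84% of those tested, and the groups did not overlap for 14.2%, where chance gives 10%. DESeq2 called 104 genes higher and 69 lower. The count of 50 was 25 without RC replicate 1, 88 without RC replicate 2, 10 without LINE1 ASO replicate 1, 5 without LINE1 ASO replicate 2 and 110 without LINE1 ASO replicate 3. The balance of directions also moved, from 74% of calls higher in the main fit to 40.9% (45 higher, 65 lower) without LINE1 ASO replicate 3. It was 47.8% (99 and 108) with no low-count filter and 100% without LINE1 ASO replicate 1 or 2. Of the 18 named genes with a call, 11, 17 and 11 kept it without RC replicates 1, 2 and 3, and 5, 4 and 18 without LINE1 ASO replicates 1, 2 and 3, all with the same sign.

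Of 20 gene lists fixed before the data were examined, 19 could be tested; the mitochondrially encoded list had 0 members in the tables. At early 2C, 7 lists stood lower than the remaining genes with the LINE1 ASO (camera, preset correlation 0.01) and 0 higher, and none of the 7 held with an estimated correlation. Replication-dependent histones had a median log2 change of -0.49 over 41 tested genes (adjusted p = 5.46e-09, and adjusted p = 0.419 with an estimated correlation), with 0 members called. Cytoplasmic ribosomal proteins had a median of -0.24 over 77 genes (adjusted p = 2.3e-08, and adjusted p = 0.628 with an estimated correlation), with 0 called over all genes and 0 higher and 1 lower adjusted over the list alone. The 2-cell-stage transcripts (genes linked to the retrovirus MERVL and targets of Dux) had a median of -0.41 over 36 genes (adjusted p = 0.00013, and adjusted p = 0.419 with an estimated correlation), with 0 called either way. Nuclear-encoded oxidative phosphorylation genes had a median of -0.20 over 73 genes (adjusted p = 0.00112, and adjusted p = 0.76 with an estimated correlation). Unfolded protein and integrated stress response genes had a median of -0.15 over 32 genes (adjusted p = 0.0238, and adjusted p = 0.625 with an estimated correlation), of which 1, Pdia4, fell and 2 were lower adjusted over the list alone. Proteasome subunits had a median of -0.13 over 37 genes (adjusted p = 0.0383, and adjusted p = 0.76 with an estimated correlation) and splicing factors -0.05 over 63 (adjusted p = 0.03, and adjusted p = 0.419 with an estimated correlation); neither held a called gene.

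Apart from Pdia4, the members of these lists with the smallest p did not pass the test over all genes. They were Hist1h4d (-0.76), Hist1h2ac (-0.57) and Hist1h2aa (-0.39) among the histones, Rpl23a (-0.90), Rpl14 (-0.74) and Rps24 (-0.54) among the ribosomal proteins, and Usp17l5 (-0.88), Spz1 (-0.92) and Zscan4e (-3.38) among the 2-cell-stage transcripts. They also held Ddit3 (-0.57) and Manf (-0.45) of the stress response, Ndufv3 (-0.93), Cox7b (-1.01) and Ndufs8 (-1.18) of oxidative phosphorylation, Psmd4 (-0.47), Psmb5 (-1.96) and Psmd6 (-0.44) of the proteasome, and Sf3b5 (-0.85), Snrnp27 (-0.36) and Snrpd1 (-0.34) of the splicing factors. The 7 list calls did not all hold when a library was left out: 3 remained without RC replicate 2 and 3 without LINE1 ASO replicate 1. The log2 changes rose with transcript length (Spearman rho 0.17 across 13459 genes) and fell slightly with GC content (rho -0.0771), and the histone and ribosomal protein genes, of median length 534 and 1059 nt, are short beside the median of 3399 nt. After a correction for length and GC content, added after the data were seen, the histone, ribosomal protein and 2-cell-stage lists kept a camera call (medians -0.243, -0.0994 and -0.341). The calls of the other lists ended: oxidative phosphorylation (median -0.0438, adjusted p = 0.175, camera), the stress response (median -0.114, 0.0814), the proteasome (-0.0236, 0.201) and splicing (-0.027, 0.0814). The stress response median had been -0.153 before the correction.

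Outside the 7 lists, 1 member of the p53 list rose, the mTOR inhibitor Ddit4 (log2 0.79, SE 0.149; adjusted p = 0.0193, edgeR), and 1 of the cell cycle list, the phosphatase Cdc25a (0.58, SE 0.103; adjusted p = 0.0127, edgeR). The adjusted camera p was 0.901 for p53 and 0.735 for the cell cycle. Adjusted over the list alone, 1 gene was higher and 1 lower in the p53 list and among the zygotic activators, 1 was higher in the cell cycle list and 1 lower among the maternal transcripts. For the other lists the adjusted camera p was 0.172 (maternal oocyte transcripts), 0.879 (zygotic activators), 0.879 (repressors of Dux and MERVL), 0.107 (ribosome biogenesis), 0.107 (interferon response), 0.104 (pluripotency), 0.137 (glycolysis), 0.611 (cumulus cell markers), 0.879 (sperm markers) and 0.735 (blood markers). Median and test or mean differed in sign for the zygotic activators (median -0.02), cell cycle (-0.01), cumulus (-0.05) and blood (0.00326) lists.

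**Figure D1:**
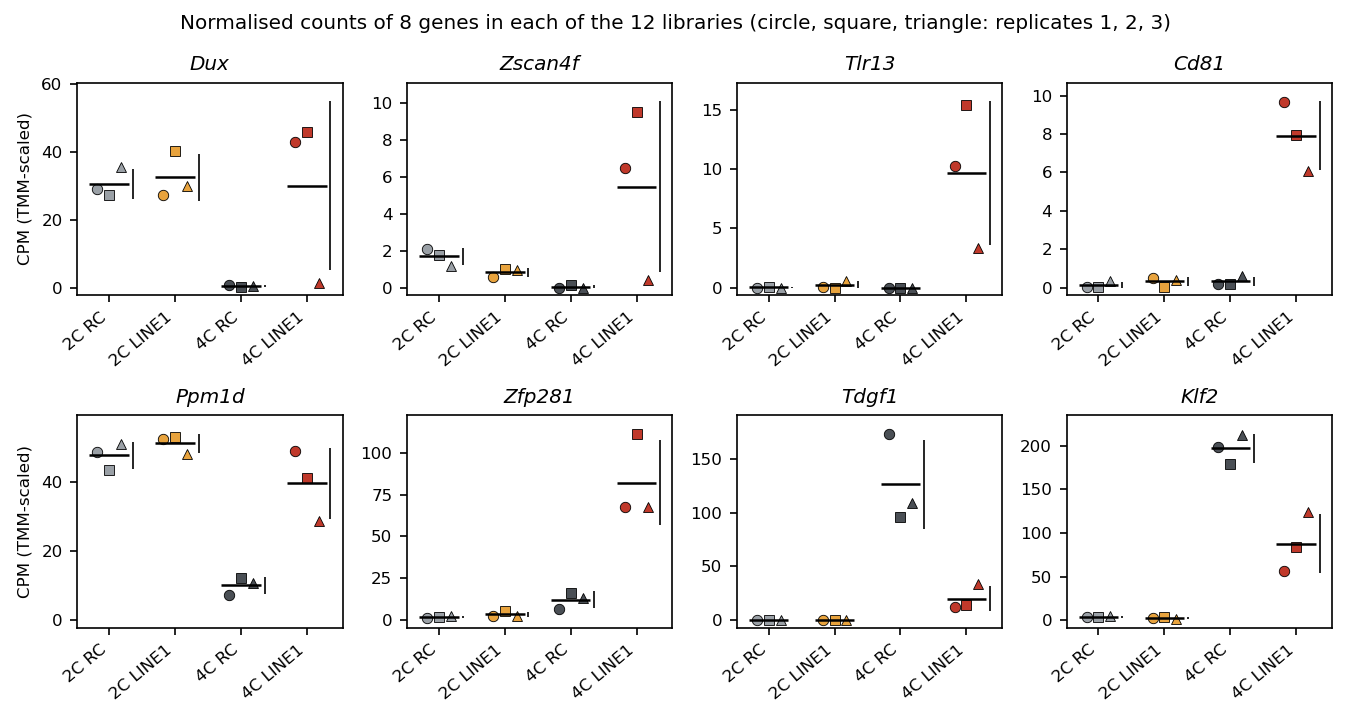
Normalised counts (CPM scaled by TMM over all 12 libraries, linear axes) of Dux, Zscan4f, Tlr13, Cd81, Ppm1d, Zfp281, Tdgf1 and Klf2, with 1 symbol per library, a horizontal line at each group's mean and a vertical line of 1 SD either side, drawn from 0 up (n = 3). Dux lay at 30.6 CPM on average in early 2C RC and 0.483 CPM in 4C RC, and in 4C LINE1 ASO the triangle, replicate 3, lies near the RC libraries for Dux and Zscan4f and apart from them for Zfp281 and Cd81. Zfp281 and Cd81 were named from a fit that counted replicate 3 as LINE1 ASO, so they do not show where it belongs.

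At 4C, the LINE1 ASO comparison gave larger differences. Tlr13, the receptor for bacterial ribosomal RNA, had 0 counts in the 3 RC libraries and 10.2 ± 6.26 CPM in the LINE1 ASO libraries (SD, n = 3), at least 206-fold higher against a floor of 3 counts over the group (adjusted p = 0.00363, edgeR). Zfp281, a zinc-finger transcription factor of pluripotent cells, rose from 13.5 ± 5.69 to 87.8 ± 25.5 CPM (log2 2.70, SE 0.325; adjusted p = 0.00363, edgeR), and the tetraspanin Cd81 from 0.359 to 8.45 CPM (log2 4.51, SE 0.615; adjusted p = 0.0105, edgeR). Tdgf1, a Nodal co-receptor, fell from 142 ± 49.05 to 21.8 ± 13.7 CPM (log2 -2.71, SE 0.414; adjusted p = 0.0172, edgeR). The pluripotency factor Klf2 fell from 220.5 to 95.01 CPM (log2 -1.21, SE 0.254; adjusted p = 0.024, edgeR).

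Among 14231 genes tested, 274 were higher and 371 lower, 645 in all (edgeR, adjusted p under 0.05). Zscan4f, a member of a cluster of near-identical 2-cell genes, had 3 counts in RC and 469 in LINE1 ASO, a ratio of 120 (counting interval 40.8 to 584; adjusted p = 0.0203, edgeR). Nacad had 1 count against 817, a ratio of 628 (112 to 24800; adjusted p = 0.0172, edgeR). Intervals and floors here cover counting error only. Other large increases under the naming rule were Ccin (log2 5.49), Sh3tc2 (4.10), the plakin Eppk1 (3.80) and the ligand Wnt7b (3.53). The largest decreases among genes that met this rule were Lmod3 (-3.20), Pros1 (-2.99), Gprc5a (-2.90), Xist (-2.89), Tdgf1, Vwa5b1 (-2.52), the bHLH inhibitor Id3 (-2.49) and Greb1l (-2.45). Dux was 5.85 higher on the log2 scale (SE 1.32), with all LINE1 ASO libraries above all RC libraries, and did not pass (adjusted p = 0.0515, edgeR). In the 6 fits without 1 library its adjusted p was 8.42e-06 without LINE1 ASO replicate 3 and over 0.05 in the other 5, up to 0.239 (edgeR). Zscan4c (5.33; adjusted p = 0.0742, edgeR), Zscan4d (2.92), Pou5f1 (-1.25; adjusted p = 0.0501, edgeR), Zfp352 (0.69), Ncl (-0.34), Trim28 (-0.44), Rn45s (-0.23) and Cdkn1a (0.91) did not pass either. Reads of the Zscan4 cluster and of the Dux array can be split between copies, so values of single copies are uncertain.

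At an unadjusted p under 0.05 there were 3156 genes at 4C, the groups did not overlap for 27.4% of genes (10% by chance), and DESeq2 called 694 higher and 834 lower. The count of 645 was 4, 15 and 117 without RC replicates 1, 2 and 3, and 11, 9 and 2126 without LINE1 ASO replicates 1, 2 and 3. The fit without LINE1 ASO replicate 3 was singled out after its values were seen; it gave 729 higher and 1397 lower. Of the 45 named genes with a call, 2, 6 and 11 kept it without RC replicates 1, 2 and 3, and 5, 5 and 45 without LINE1 ASO replicates 1, 2 and 3, all with the same sign. Tlr13 and Zfp281 kept theirs in all 6 of these fits. Scaling by library totals gave 563 higher and 239 lower, 70.2% higher against 42.5%, and a joint fit of the 12 libraries 64.1%. Library totals moved the median log2 change of all genes by 0.181 at 4C, by 0.188 in the developmental comparison and by 0.147 in the interaction, so directions are relative to the TMM scale.

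Among the fixed lists at 4C, the 2-cell-stage transcripts and the p53 response stood higher than other genes and 6 lists lower (camera). The adjusted p was 0.535 with an estimated correlation for each of the 8, so none held there. Of the p53 response genes, 7 of 34 tested rose and 0 fell, and 12 were higher and 1 lower adjusted over the list alone (median 0.54, camera adjusted p = 9.15e-06). Ppm1d, a phosphatase that restrains p53, rose from 11.3 to 42.4 CPM (log2 1.91, SE 0.289; adjusted p = 0.0144, edgeR). Ccng1 rose by 1.37 (adjusted p = 0.0232, edgeR) and Ddit4 by 1.35 (adjusted p = 0.0172, edgeR). Of the 2-cell-stage transcripts, 2 of 40 tested rose, Zscan4f and BC080695 (3.16), and 1 fell, the choline kinase Chka (-0.91). Each of the 3 lost its call in 5 of the 6 fits without 1 library and kept it only without LINE1 ASO replicate 3. In LINE1 ASO replicates 1, 2 and 3, Zscan4f had 6.87, 9.96 and 0.443 CPM (at most 0.161 in RC) and BC080695 20.6, 17.8 and 2.78 CPM (at most 2.47 in RC). Adjusted over the list alone 13 were higher and 2 lower (median 1.43, camera adjusted p = 0.000249). Many of this list, such as Zscan4, Tdpoz, Usp17l and the Eif1a-like genes, belong to multicopy families. The adjusted camera p of the 2-cell-stage list was at most 0.0464 when any 1 of the 6 libraries was left out.

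Among the 6 lists that stood lower at 4C, cytoplasmic ribosomal proteins had a median of -0.42, with 77 of 79 tested genes negative (camera adjusted p = 4.8e-12). Of these, 3 fell, Rpl3 (-1.06), Rpl10 (-0.82) and Rpl36a (-0.68), and 5 were lower adjusted over the list alone. Pseudogene copies make single values uncertain. The correction for transcript length and GC content was run only at early 2C, so such a trend is not excluded for these short genes at 4C. Ribosome biogenesis genes had a median of -0.29 over 102 genes (camera adjusted p = 2.26e-08): 7 fell, among them Ddx47 (-0.996), Ddx10 (-0.94) and Riok2 (-0.85), and 1 rose, with 18 lower and 1 higher adjusted over the list alone. Cell cycle genes had a median of -0.40 over 55 genes (camera adjusted p = 2.26e-08). Of these, 9 fell and 0 rose, among them the kinetochore genes Ndc80 (-1.16) and Cenpe (-0.92) and the ribonucleotide reductase subunit Rrm2 (-0.98), with 19 lower and 1 higher adjusted over the list alone. Pluripotency and early lineage regulators had a median of -0.66 over 32 genes (camera adjusted p = 0.000225), and 3 fell, Tdgf1, Tfap2c (-1.07) and Klf2, with 9 lower and 1 higher adjusted over the list alone. Of 25 zygotic activators and homeobox regulators, 1 rose, Zfp281, and 6 fell, among them Trim24 (-1.16) and Obox6 (-0.99), with 2 higher and 7 lower adjusted over the list alone (median -0.32, camera adjusted p = 0.00368). Splicing factors had a median of -0.13 over 63 genes (camera adjusted p = 0.0079). Of these, 3 fell, with Snrnp200 (-1.11) and Srsf9 (-0.996), and 1 rose, Cdc5l (0.95), with 5 lower and 1 higher adjusted over the list alone. The splicing call was lost without RC replicate 1 (adjusted p = 0.196), the highest of the 6 such fits, and its median was 0.05 with library totals (adjusted p = 0.105).

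**Figure D2:**
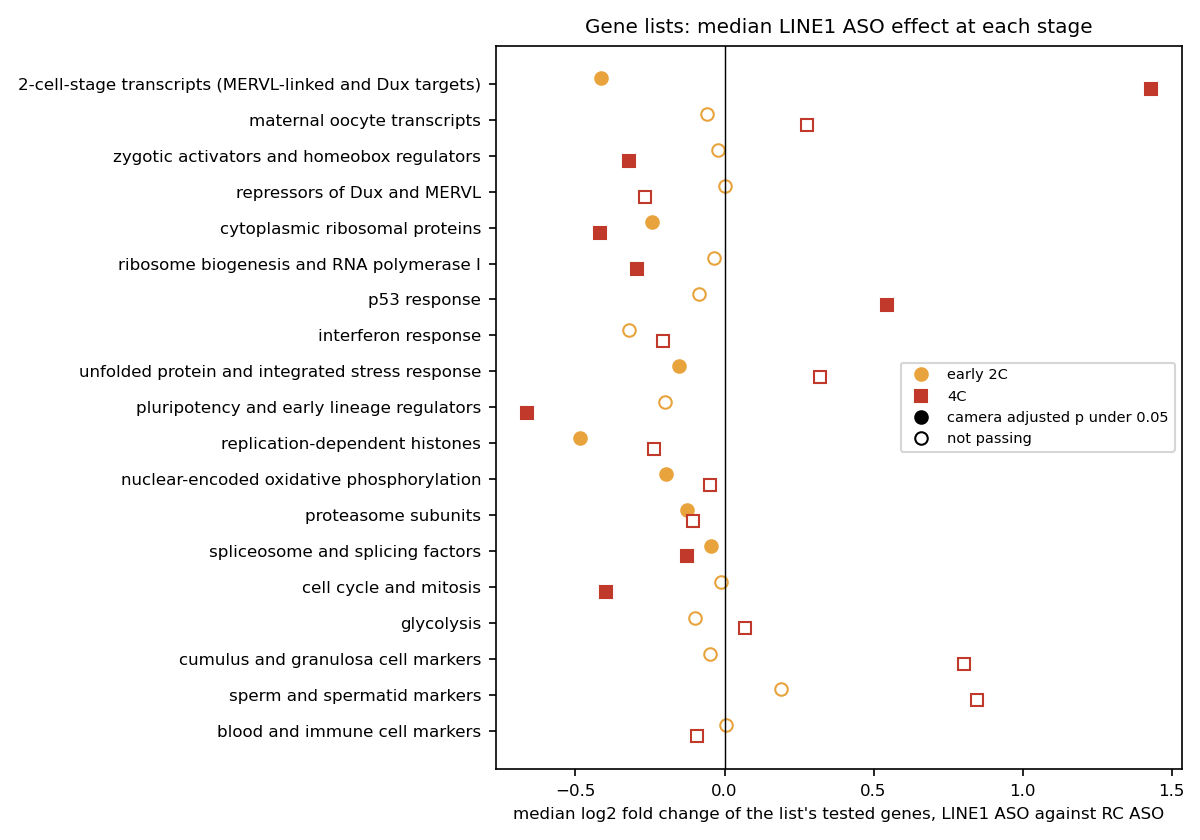
Median log2 fold change of LINE1 ASO against RC ASO for the tested genes of each of the 19 lists, at early 2C (circles) and at 4C (squares); filled symbols mark a camera adjusted p under 0.05 with the preset correlation, and none of these held with an estimated correlation. The 2-cell-stage list lies at -0.413 at early 2C and at 1.43 at 4C, and the pluripotency list at -0.663 at 4C; the splicing list turns positive at 4C with library totals (0.0495).

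The other lists did not pass at 4C. Maternal oocyte transcripts had a camera adjusted p of 0.0725 with 1 member higher, Oosp1 (1.49), and repressors of Dux and MERVL had 0.0725 with the imprint regulator Zfp57 higher (1.09) and the polycomb factor Rybp lower (-0.71), or 2 higher and 3 lower adjusted over the list alone. Proteasome subunits had 0.0704 with Psmd8 (-1.21) and Psmd14 (-0.67) lower, and glycolysis 0.871 with Hk1 lower (-1.75) and Ldhb higher (0.81). The adjusted p was 0.443 for interferon response, 0.082 for histones and 0.515 for oxidative phosphorylation, none with a called member. It was 0.0536 for the unfolded protein and integrated stress response, with 0 called; this list, with a median of 0.32, was the 1 that passed fry at 4C (adjusted p = 0.0298). The cumulus (0.43), sperm (0.146) and blood (0.988) marker lists held no called gene, with 10, 5 and 6 genes tested, and 1 sperm marker was higher adjusted over the list alone. For the remaining lists that did not pass, the counts adjusted over the list alone were the same as over all genes, except that Oosp1 was not called there. Median and mean differed in sign for glycolysis (0.07 and -0.07) and blood markers (-0.09 and 0.03). With library totals the medians of the oxidative phosphorylation (0.135), proteasome (0.0834) and blood (0.102) lists were positive.

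The third comparison described development under the control ASO, from early 2C RC to 4C RC. Fgf4, a growth factor of the early lineages, had 0 counts at early 2C and 46.3 ± 7.93 CPM at 4C (SD, n = 3), at least 1191-fold higher. Atg4d, an autophagy protease, was at least 478-fold higher and the cytokine gene Flt3l at least 402-fold. Tdgf1 had 2 counts at early 2C and 8487 at 4C (ratio 4850, counting interval 1340 to 40000), and Fkbp10 1 and 4469 (5110, 916 to 202000). In the other direction Calb1 was at least 493-fold lower, Fam187b 287-fold, Aadac 211-fold, Slc9a4 208-fold and Asb15 204-fold, each with 0 counts at 4C.

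In total 5690 genes rose and 5765 fell among 15760 tested (edgeR, adjusted p under 0.05), and the groups did not overlap for 76% of genes (10% by chance). Dux fell from 30.6 ± 4.40 to 0.483 ± 0.356 CPM (log2 -5.96, SE 0.961; adjusted p = 4.14e-05, edgeR), with Zscan4d (-3.93) and Zscan4c (-3.76). Cdkn1a rose by 5.99 (SE 0.540; adjusted p = 6.46e-08, edgeR), Rn45s by 3.42, Trim28 by 2.85 and Ncl by 1.78, while Pou5f1 fell (-0.85; adjusted p = 0.012, edgeR) and Zfp352 did not pass (-0.12; adjusted p = 0.86, edgeR). Without 1 library, the call of Pou5f1 was lost without early 2C RC replicate 2 (adjusted p = 0.0636, edgeR) or 4C RC replicate 2, and that of Zscan4c without 4C RC replicate 3 (0.051).

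Of 55 maternal oocyte transcripts, 51 fell and 2 rose from early 2C to 4C (median -4.38, camera adjusted p = 1.87e-26, and adjusted p = 0.155 with an estimated correlation), with 52 and 2 adjusted over the list alone. All 79 ribosomal protein genes rose, also adjusted over the list alone (median 4.29, camera adjusted p = 3.23e-39, and adjusted p = 0.155 with an estimated correlation). Ribosome biogenesis genes rose in 90 cases and fell in 2 of 102 (median 2.46; adjusted p = 2.44e-21, and adjusted p = 0.108 with an estimated correlation), spliceosome genes in 40 and 8 of 63 (0.84; adjusted p = 8.4e-05, and adjusted p = 0.269 with an estimated correlation) and proteasome genes in 29 and 3 of 38 (1.57; adjusted p = 6.96e-05, and adjusted p = 0.208 with an estimated correlation). Oxidative phosphorylation genes rose in 52 and fell in 9 of 74 cases (1.52; adjusted p = 0.000812, and adjusted p = 0.613 with an estimated correlation). Zygotic activators rose in 16 and fell in 8 of 25 (2.61; adjusted p = 0.00817, and adjusted p = 0.155 with an estimated correlation) and p53 response genes in 21 and 6 of 34 (1.96; adjusted p = 0.0221, and adjusted p = 0.613 with an estimated correlation). The counts of these last 6 lists were the same adjusted over the list alone.

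In the lists that did not pass in development, calls over all genes went both ways, except for the sperm markers. The 2-cell-stage list held 17 that rose and 11 that fell of 42 (adjusted p = 0.196), repressors of Dux and MERVL 21 and 12 of 36 (0.283), cell cycle 27 and 16 of 55 (0.196), histones 31 and 8 of 53 (0.0633) and pluripotency 18 and 9 of 32 (0.062). The stress response held 13 and 8 of 32 (0.196), interferon response 7 and 5 of 20 (0.307), glycolysis 6 and 8 of 17 (0.6), cumulus 1 and 2 of 15 (0.856), sperm 0 and 5 of 8 (0.423) and blood 2 and 2 of 9 (0.856). Adjusted over the list alone the counts were the same, except for 1 and 0 cumulus and 0 and 4 sperm markers. Median and mean or test differed in sign for the stress response (median -0.09, mean 0.53), blood (0.22 and -0.18) and cumulus lists. The medians of the stress response (0.12) and cumulus (0.04) lists were positive with library totals.

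The LINE1 ASO effect at 4C was then set against this developmental change, across 15344 genes, which are not independent replicates. Pearson's r was -0.366 and Spearman's rho -0.388: genes that fall from early 2C to 4C tended to be higher in 4C LINE1 ASO embryos. Both contrasts use the 4C RC libraries. In 100 simulated sets with no LINE1 ASO effect r was -0.115 to -0.0734, and the observed covariance of -0.969 exceeded the simulated median of -0.145 by -0.824. With no library shared between the contrasts, r was -0.258 and the covariance -0.746, against -0.0388 to 0.0323 in the simulated sets. The simulated sets here and below drew each gene on its own, so their ranges leave out differences between libraries that many genes share. Whether such a difference between the few libraries of each group contributed was not tested. Of 274 genes higher with the LINE1 ASO, 161 fell in development (93.4 for independent lists) and 65 rose (109), and of 371 lower genes, 302 rose (148) and 31 fell (126). In 50 simulated sets with no LINE1 ASO effect at most 1 gene was called at 4C, so that these overlaps were 0 or 1; neither value counts the shared libraries together with real effects, and part of the excess may come from the shared libraries. The median LINE1 ASO effect was 0.306 for the 4850 genes that fell (0.00522 to 0.0263 in the simulated sets) and -0.205 for the 5682 that rose (-0.0308 to -0.0089). Zscan4f and Nacad were among the genes that fell and were higher, Tdgf1 among those that rose and were lower, and Zfp281 lay off this line, higher in both contrasts.

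**Figure D3:**
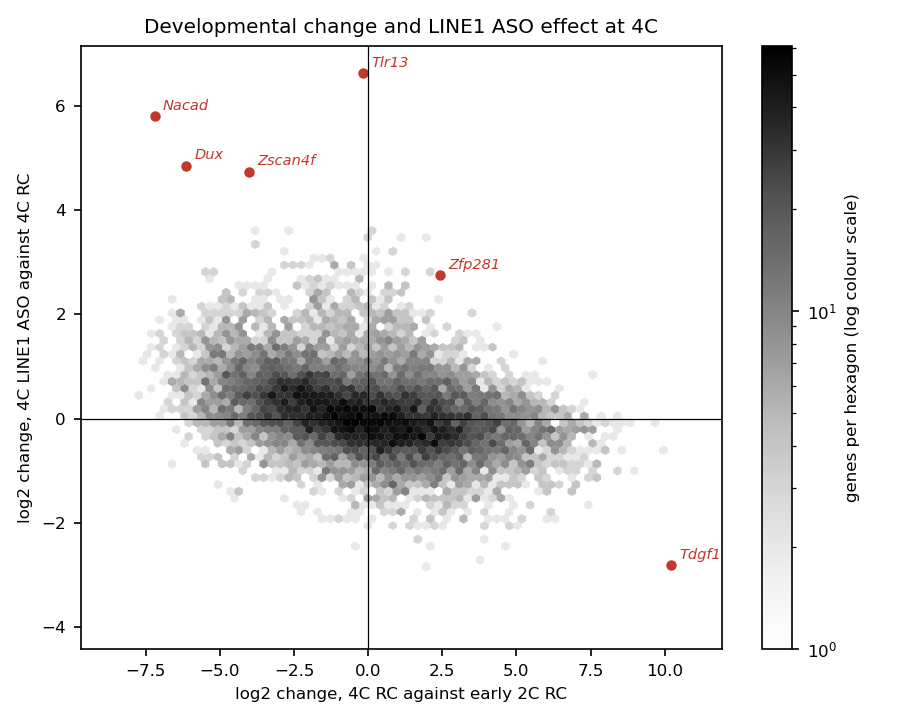
Change from early 2C RC to 4C RC (x axis) against the change from 4C RC to 4C LINE1 ASO (y axis), both as differences of mean log2 CPM with a prior count of 2, for 15344 genes as hexagons shaded by gene number on a log colour scale, with 6 genes marked. The cloud falls from upper left to lower right (r = -0.366, across genes), with part of the slope due to the shared RC libraries (simulated r -0.0927).

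The interaction asked whether the LINE1 ASO effect differed between the stages. Its fit shares 1 estimate of the spread. The common coefficient of variation was 0.379 in it, against 0.229 at early 2C and 0.412 at 4C in the separate fits. A joint fit of the 12 libraries called 1714 genes at 4C against 645, and 2 at early 2C against 50. Interaction calls that rest on a 4C difference may therefore pass too easily. Prkab1 rose at early 2C and was lower at 4C (log2 -0.95; adjusted p = 0.0182, edgeR), a difference of -2.27 (SE 0.248; adjusted p = 0.0011, edgeR). For Dux the effect was 5.85 larger at 4C than at early 2C (SE 1.18; adjusted p = 0.0386, edgeR). This call was lost when any of 10 of the 12 libraries was left out, with an adjusted p between 0.0535 and 0.101 in those fits, and held without 4C RC replicate 3 (0.0427) or 4C LINE1 ASO replicate 3 (2.43e-05). It was also lost with no low-count filter (adjusted p = 0.077, edgeR) and with a replicate block (adjusted p = 0.0879, edgeR). Zscan4f also differed (fitted log2 difference 7.79; adjusted p = 0.0386, edgeR), while Zscan4c (5.98; adjusted p = 0.0883, edgeR), Zscan4d (3.68), Zfp352 (0.84), Ncl (-0.30), Trim28 (-0.44), Rn45s (-0.23), Pou5f1 (-0.90) and Cdkn1a (0.86) did not pass.

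In all 102 differences were positive and 74 negative, 176 of 15760 genes (edgeR, adjusted p under 0.05), with 2757 genes at an unadjusted p under 0.05 and 482 and 449 called by DESeq2. At 4C, Epb4.2 had 0 counts in RC and 78 in LINE1 ASO, at least 20.8-fold higher, and Kcnmb2 0 and 58, at least 15.5-fold. Nacad, described above, differed as well. Apobec3, a cytidine deaminase that restricts retroelements, had 57 counts in early 2C RC and 0 in early 2C LINE1 ASO, at least 24.5-fold lower. Zkscan3 had 3 and 57 counts there (ratio 14.7, counting interval 4.79 to 73.4). Neither Apobec3 nor Zkscan3 was among the 50 genes called in the early 2C comparison itself, and their calls here come from the fit of all 12 libraries. Gls2 (-3.17), Zfp874b (-2.74) and Lrp2 (-2.43) followed among the negative differences of genes that met the naming rule. Nacad, Apobec3 and Prkab1 kept their call in each of the 12 fits without 1 library, while Epb4.2 lost it in 1, Zkscan3 and Lrp2 in 8, Zscan4f in 9, Gls2 and Zfp874b in 10 and Kcnmb2 in 11. The median difference over all genes was 0.187. It was -0.0274 to 0.0495 when any 1 early 2C library was left out, with a median shift of the differences of -0.203 to -0.152. The share of positive differences among the calls was then 42.1 to 57.7%. The sign and size of small interaction differences, list medians included, therefore rest on the scaling of the full fit. Scaling by library totals gave 224 positive and 53 negative differences (80.9% positive against 58%), and DESeq2 size factors 80 and 109 (42.3%). The count of 176 was 38, 26 and 27 without early 2C RC replicates 1, 2 and 3, and 22, 19 and 30 without early 2C LINE1 ASO replicates 1, 2 and 3. It was 48 and 358 without 4C RC replicates 1 and 3, and 33, 28 and 1297 without 4C LINE1 ASO replicates 1, 2 and 3.

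Of the lists, 9 passed camera in the interaction, none with an estimated correlation. The effect at 4C lay above that at early 2C for the 2-cell-stage list (median difference 1.79; adjusted p = 7.11e-05, and adjusted p = 0.701 with an estimated correlation), the p53 response (0.59; adjusted p = 0.000442, and adjusted p = 0.639 with an estimated correlation), the stress response (0.48; adjusted p = 0.0211, and adjusted p = 0.492 with an estimated correlation) and the maternal transcripts (0.33; adjusted p = 0.0211, and adjusted p = 0.792 with an estimated correlation). It lay below for the cell cycle (-0.34; adjusted p = 1.97e-08, and adjusted p = 0.327 with an estimated correlation), ribosome biogenesis (-0.22; adjusted p = 4.76e-05, and adjusted p = 0.492 with an estimated correlation) and pluripotency lists (-0.32; adjusted p = 0.0281, and adjusted p = 0.701 with an estimated correlation). The zygotic activators (-0.26; adjusted p = 0.025, and adjusted p = 0.492 with an estimated correlation) and ribosomal proteins (-0.08; adjusted p = 0.025, and adjusted p = 0.848 with an estimated correlation) also lay below. The last 2 calls were lost with library totals (adjusted p = 0.0756 and 0.113), where the ribosomal protein median was 0.08. Called members were few: 2 higher in the 2-cell-stage list and 17 higher and 3 lower adjusted over the list alone, 3 higher in the p53 list (10 and 1), 1 higher in the stress response (3 and 0), 2 lower in the cell cycle list (1 and 12), 1 lower among the zygotic activators (3 and 3), 1 lower in the pluripotency list (0 and 1), and 0 among maternal transcripts (0 and 0), ribosomal proteins (0 and 0) and ribosome biogenesis genes (1 and 6). Over the 12 leave-one-out fits the 2-cell-stage, p53, cell cycle and ribosome biogenesis calls were never lost, and the maternal call was lost in 8, the pluripotency call in 7, the ribosomal protein and stress response calls in 4 each and the zygotic activator call in 3.

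For the remaining lists the adjusted camera p of the interaction was 0.156 (repressors of Dux and MERVL), 0.844 (interferon), 0.674 (histones), 0.46 (oxidative phosphorylation), 0.844 (proteasome), 0.131 (splicing), 0.538 (glycolysis), 0.425 (cumulus), 0.552 (sperm) and 0.866 (blood). Of their members 2 repressors and 1 glycolysis gene were higher over all genes, and adjusted over the list alone 2 repressors were higher and 1 lower, 2 glycolysis genes higher, and 1 splicing and 1 sperm gene higher. Median and test or mean differed in sign for the proteasome (0.14), splicing (0.02) and blood (0.30) lists, and the splicing median was -0.07 with DESeq2 size factors, where its adjusted p was 0.0362.

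Across the 12312 genes tested at both stages the LINE1 ASO effects hardly correlated (Pearson's r 0.0441, Spearman's rho 0.0826), with no library shared between the stages. Most of these genes were called at neither stage, and r was 0.087 with a stricter low-count filter. A low r over all genes therefore does not show that the effects are unrelated. Still, 6 genes were higher at both: Dcp1a, Ddit4, Fam84b, the forkhead factor Foxk1, the Rag GTPase Rragc and the TGF-beta effector Smad3, where independent lists give 0.754 (Fisher's exact test, two-sided p = 9.25e-05). Fisher's test counts genes as independent replicates, which they are not, so its p here and below is descriptive. Rragc rose by 0.67 at early 2C and 1.77 at 4C, and Dcp1a by 1.14 and 1.38. The cohesin subunit Smc1a was lower at both (-0.56 and -1.47), 1 gene against 0.355 for independent lists (Fisher's exact p = 0.302). Prkab1, Ss18 and Ypel2 were called in opposite directions, higher at early 2C and lower at 4C. Shared calls were thus not confined to the same direction, and no expected number was computed for the opposite ones. Of the 50 genes called at early 2C, 36 had the same sign at 4C. These shared genes were named because of their calls, after their values were seen.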

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

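The tests of mixed early 2C RNA and of depth and the equal-axes placements of 4C LINE1 ASO replicate 3 were chosen only after the result was seen, and the length and GC correction was added after the data were seen, with its bound written before its result. The results in the next 2 paragraphs stood out because the LINE1 ASO effect differed between the stages (edgeR interaction, adjusted p under 0.05, or camera for lists). Values are log2 effects at 4C minus those at early 2C.

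Positive differences were found for Nacad (9.341), Epb4.2 (7.817), Zscan4f (7.791), Kcnmb2 (7.312), Apobec3 (7.172), Dux (5.851), Sh3tc2 (4.136), Ppm1d (1.869), Zfp57 (1.321), Manf (1.204), Ldhb (0.9912) and Cep250 (0.829). Negative differences were found for Zkscan3 (-5.308), Gls2 (-3.17), Zfp874b (-2.737), Lrp2 (-2.433), Prkab1 (-2.275), Cdc25a (-1.602), Phf13 (-1.332), Ccdc117 (-1.293), Atl3 (-1.273), Tfap2c (-1.177) and Rrm2 (-1.123). Values of genes with 0 to 3 counts in a group are fitted and no bounds.

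Among lists, the median difference was 1.79 for the 2-cell-stage transcripts, 0.589 for the p53 response, 0.476 for the stress response and 0.325 for maternal transcripts. It was -0.336 for the cell cycle, -0.324 for pluripotency, -0.255 for zygotic activators, -0.223 for ribosome biogenesis and -0.0807 for ribosomal proteins (0.076 with library totals). None of these 9 lists passed with an estimated correlation (camera, adjusted p from 0.327 to 0.848 over all lists). Of 100 splits of the libraries within stage, 3 called at least as many genes as the real one, itself included (real 176, highest other 320). The 91 splits that mixed the 4C groups, and so removed the 4C effect itself, called 0 to 3 genes. Of the 8 others that kept these groups together, with 27 to 320 calls, 2 called at least as many as the real one. The count followed a structure of the samples, the 4C groups, and does not exclude chance for a difference between the stages. At early 2C the real split called 50 genes and the highest other 17 (1 of 10 splits as large). At 4C these were 645 and 0 (1 of 10), and in development 11455 and 0 (1 of 10). With 10 splits the share cannot fall under 0.05.

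The first pattern weighed is that genes that fall from early 2C to 4C tended to be higher in 4C LINE1 ASO libraries, as was the 2-cell-stage list, which itself moves both ways in development. The shared RC libraries are argued against as the whole cause, since the covariance was -0.746 with no library shared, outside the -0.0388 to 0.0323 of simulated data. That range was simulated gene by gene, so a difference between libraries that many genes share is not excluded. Early 2C embryos in the 4C LINE1 ASO pools would bring all abundant early 2C transcripts, 50 of which allowed a median of 0.959% early 2C RNA and a 95th percentile of 7.12%, against a median of 98%, the value of Dux, for the 9 falling list members. This argues against such a mixture for Dux and the summed Zscan4 copies in LINE1 ASO replicates 1 and 2, where each needed at least 141% and no abundant transcript over 15.3%; it stays open for replicate 3, where Dux (2.60%) and Zscan4 (6.01%) lay above the 95th percentile of abundant transcripts (2.35%; highest 3.73%) but above the RC libraries (-1.29 to 1.02% and -7.24 to 5.15%) by less than their range, and for the other 3 falling members, Zfp750, Arg2 and Cyp2b23 (2.76, -5.73 and -10%). A slower passage through the 2-cell stage, or 2-cell embryos later than those sampled, may account for it; this was not tested and stays open as a hypothesis.

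The second pattern is that 4C LINE1 ASO replicate 3 lay between the RC libraries and the other LINE1 ASO libraries. Its depth was 1.08 times the mean of the other 5 libraries, which argues against lower depth. If it were an RC library under a LINE1 ASO label, it would lie among the RC libraries, and the placement fixed beforehand put it there, at 0.353 within 0.0913 to 0.359. That placement counted replicate 3 as LINE1 ASO when placing the RC libraries; on equal axes replicate 3 lay above all 3 RC libraries in each of 11 measures, at 0.428 against -0.114 to 0.166 over called genes and beyond the other 3 for 71.4% of these against 8.01 to 41.5%, both by less than the RC range. The excess passed that range, the bound set beforehand for the first placement, only in 4 measures that count large folds (over 4-fold beyond for 1.65% of genes against 0.216 to 0.557%). All 11 measures use the same libraries and were tried after the first placement was seen, and some library must lie highest in each. These values therefore do not decide for or against a wrong label. A wrong and a right label cannot be told apart with 3 RC libraries and measures that disagree. Less delivered ASO, which was not tested, may also account for the position of replicate 3.

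The third pattern is that 7 lists were lower with the LINE1 ASO at early 2C. After correction for transcript length and GC content 3 of the 7 kept a camera call, with medians moving from -0.425 to -0.341 for the 2-cell-stage list, from -0.242 to -0.0994 for ribosomal proteins and from -0.486 to -0.243 for histones. The other calls ended as the medians moved towards 0: from -0.197 to -0.0438 for oxidative phosphorylation (camera, adjusted p = 0.175 after correction), from -0.153 to -0.114 for the stress response (0.0814), from -0.127 to -0.0236 for the proteasome (0.201) and from -0.0451 to -0.027 for splicing (0.0814). Without RC replicate 2, 3 also kept it: the 2-cell-stage, histone and splicing lists. Each explanation may account for part of the lists, and with 3 libraries per group neither can be told apart from an effect of the ASO.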

How the results depend on the processing

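The length and GC correction was chosen only after the data were seen; every other setting here was planned. At early 2C, 50 called genes became 207 with no low-count filter, 80 with a replicate block, 2 in a joint fit of the 12 libraries, 173 with DESeq2, 4 with an absolute log2 fold change of at least 1 and 5 to 110 without 1 library. At 4C, 645 became 1108, 1504, 1714, 1528 and 429 in the same order, and 4 to 2126 without 1 library. All 50 and all 645 were among the DESeq2 calls. The interaction's 176 became 277 with library totals, 12 with a replicate block (Dux lost its call, edgeR adjusted p = 0.0879), 931 with DESeq2 and 19 to 1297 without 1 library. Replicate numbers gave no clear pairing of these samples: same-number correlations of deviations were 0.02, -0.0263 and -0.059 at early 2C and 0.0101, 0.168 and 0.0971 at 4C, and not every sample correlated best with its own number. At 4C, LINE1 ASO replicates 2 and 3 did correlate best with the RC library of their number, and replicate 1 did not, so pairing at 4C is not excluded. Counts of developmental calls stayed within 1.5 times in all settings run.

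With an estimated inter-gene correlation 0 lists passed at early 2C, 0 at 4C, 0 in development and 0 in the interaction, and with fry 0, 1, 17 and 2. Without 1 library 3 to 9 lists passed at early 2C (main 7), 7 to 13 at 4C (8) and 5 to 10 in the interaction (9), and 3 passed at early 2C after the length and GC correction. The correlation between stages was 0.08697 with a stricter filter and 0.02134 to 0.04458 without 1 library (main 0.0441). The relation to development was -0.4067 with a stricter filter, -0.2576 with no shared library and -0.3971 to -0.3202 without 1 library (main -0.366). For named genes, 509 values kept their side of the threshold, 15 lost and 23 gained a call. These counts cover DESeq2, its size factors in edgeR, no low-count filter and a replicate block. Without 1 library they were 739, 308 and 15. The remaining settings were not counted for named genes. In the joint fit of the 12 libraries, only 1 of all 50 early 2C calls and 561 of all 645 4C calls were kept. The cause of each change was not tested. The fits without 1 library held fewer libraries, yet some called more genes, such as 2126 against 645 at 4C without LINE1 ASO replicate 3.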

Other observations

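The test of the p53 position was chosen only after the result was seen; that of the decay factors was chosen beforehand. Xist, the RNA that silences an X chromosome, was lower in 4C LINE1 ASO embryos (log2 -2.89, adjusted p = 0.0382, edgeR), at 188, 840 and 249 CPM in the RC libraries and 57.9, 49.3 and 65.2 CPM in the LINE1 ASO libraries. The Y-linked genes Ddx3y (-0.54), Eif2s3y (-0.27), Kdm5d (0.34) and Uty (-0.31) did not pass, and Ddx3y and Eif2s3y were lowest in RC replicate 2 (6.56 and 3.98 CPM), the library highest in Xist. Kdm5d and Uty were instead lowest in LINE1 ASO replicate 2 (4.49 and 2.40 CPM, against 5.49 and 2.85 CPM in RC replicate 2), the library lowest in Xist. Ccdc82 took 1.02, 1.36 and 1.08% of the counts in 4C RC and 2.38, 1.90 and 1.32% in 4C LINE1 ASO libraries.

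Of the p53 list at 4C, Mdm2 (0.87), Bbc3 (1.99), Pmaip1 (2.43) and Phlda3 (1.91) also rose; they fall outside the rule for named genes and were chosen after their values were seen. One hypothesis was that the higher p53 list reflects an earlier position on the normal path. Members that rise from early 2C to 4C would then be lower in LINE1 ASO embryos. The median effect of these 21 members was 0.538 (bootstrap SE 0.246), 18 were positive and 5 were called higher. Only 7 of the 34 tested members of the list were negative at 4C, so a median below 0 could not occur. The bootstrap resampled genes of the same libraries and not libraries. These rising members were thus mostly higher, but the test cannot decide on the hypothesis.

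At early 2C the nonsense-mediated decay genes Upf1 (0.80) and Smg1 (0.44) rose with Dcp1a (1.14). A joint rise of the decay and decapping factors was tested as a hypothesis on the other members fixed beforehand: of 11 tested, 3 were positive and 8 negative, 0 were called, and the camera p was 0.708, which gives no sign of one.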
